A study of Cellvibrio japonicus with 12 samples.

How the data were processed

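RNA was sequenced from Cellvibrio japonicus Ueda107, a soil bacterium that degrades plant cell wall polysaccharides. Wild-type cells grew in a defined MOPS medium with mannan or glucose as the carbon source, and RNA was taken in exponential and in stationary phase after the cells had been fixed in ethanol and phenol, per the labels' protocols. The 12 libraries form 4 groups of 3, which the series describes as biological triplicates, so p-values measure the spread between these cultures. The design text calls the mannan substrate glucomannan. The 6 glucose libraries were re-used from an earlier series, so carbon source and experiment cannot be told apart in any comparison of mannan with glucose.

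The submitters' processing notes name HISAT2, HTSeq and DESeq2, with no roles or versions, and the genome build is not given in the sources used here. Per the file headers, the deposited tables hold read counts per gene, as unique and as total gene reads, for each library. The deposited RPKM values divide those reads by gene length and by the library's reads over all features; recomputing them from the counts gave a largest relative deviation of 1.42e-15. The deposited normalized expression values are log-transformed and quantile-normalized, per the file headers, and the authors' differences between group means, taken as log2 values, gave only the direction of their calls. The deposited p-values of each pairwise comparison come with false discovery rates, per the file headers, and are quoted only as the authors' own. The headers place this test on the normalized values, not on read counts, and do not name DESeq2. A p-value was absent for 33 features in exponential phase, 33 between phases on mannan and 636 in stationary phase. Counts of features from this test and from edgeR thus differ in method, scaling and features tested. The 18 library columns that 2 tables share held equal values. Coordinates are as the authors' files give them.

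Each table lists 3812 features. Of these, 3574 were matched to the RefSeq annotation of assembly ASM1922v1, 2357 by locus tag and 1217 by coordinates, and 238 were not matched; 98.5% of the tag-matched features shared a start or end. The annotation was used only for symbols, biotype and neighbouring genes. The 57 structural RNA features (among them 9 rRNA, 46 tRNA and 1 tmRNA) stayed in the tests. A level is given in RPM, computed here with the library's reads outside structural RNA as the total, as mean ± SD with n = 3.

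Differential expression was tested on total gene reads with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test after filterByExpr and TMM normalization, in a fit of the 2 groups compared. The interaction of carbon source and phase was fitted over all 12 libraries. Every adjusted p for a gene is from this edgeR test with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 changes are followed by ± the standard error, taken as the change divided by the square root of F. Because TMM factors differ from reads outside structural RNA, a log2 change differs from the log2 ratio of the printed levels by a constant, which was -0.30 for mannan against glucose in exponential phase, -0.52 in stationary phase, -0.28 for stationary against exponential phase on mannan and 0.09 on glucose.

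Gene lists for polysaccharide degradation, central metabolism, translation, motility, secretion and stress were fixed before the data were examined, as were the groups, the tests, the rule for named genes and most of the other settings tried. Of 28 lists, 25 had at least 3 members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 25 lists within a comparison; camera with an estimated correlation and fry were the alternatives. The genes psd and cysS were taken out of the amino acid list after its membership had been seen and before any test.

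The rule named up to 10 tested members of the mannan list, the 8 largest rises and 8 largest falls by log2 change among called protein-coding genes with a mean of at least 10 RPM and groups that did not overlap, and the 3 members with the smallest adjusted p of each list that passed camera; for the interaction it named 5 and 5, with no rule on overlap. Chance gives groups of 3 that do not overlap in 10% of genes. Protein-coding was read as the RefSeq biotype only after the ranks under a wider reading, any feature outside structural RNA, had been seen. The wider reading also names CJA_0245 and CJA_3308 in exponential phase on mannan; CJA_0026, CJA_0034, CJA_0933, CJA_1852, CJA_3059, CJA_3308, CJA_3533 and CJA_0381 in stationary phase; CJA_0065, CJA_1425, CJA_0893, CJA_3860 and CJA_3882 between phases; and CJA_0026 and CJA_1305 in the interaction. Groups of neighbouring genes were chosen after their values had been seen.

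The other settings chosen in advance began with median-ratio size factors (RLE) in edgeR, library sizes with no composition factor, DESeq2 1.42.0 and no count filter. In a further setting the rRNA and tRNA features were left out before normalization, with the tmRNA kept. The rest were each library left out in turn, the replicate number as a block, all 4 groups in 1 fit and a stricter threshold (adjusted p under 0.01 and an absolute log2 change of at least 2). Unique gene reads and libraries thinned to 172856 reads outside structural RNA were added after the data had been seen. The procedure was tested on simulated data drawn from the real means, with 200 changed genes. Of genes changed 2-fold it called 97.0% for mannan against glucose in exponential phase, 13.4% in stationary phase, 58.2% between phases on mannan, 58.2% between phases on glucose and 14.9% in the interaction; at 4-fold the shares were 100%, 80.3%, 97.0%, 92.4% and 74.2%. False calls made up 3.76%, 4.62%, 10%, 2.56% and 4.76% of the calls in these simulations. Between phases on mannan (12 false calls) their share was thus above the 0.05 threshold. Because the real fits called 1724 to 2569 genes, far more than the 200 changed here in random directions, these shares need not carry over to the data. A fold against a group with 1 to 3 reads is given as the ratio of pooled reads with an exact 95% conditional interval. Intervals and floors cover counting error only. Tables were handled and drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.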

Results

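Transcripts of Cellvibrio japonicus were counted over 3812 features in 12 libraries, 3 each from mannan and glucose cultures in exponential and in stationary phase. Gene reads per library ranged from 8649484 to 12131830. Ribosomal RNA took 0.996% ± 0.0361 of the reads in mannan exponential libraries (mean ± SD, n = 3), 1.84% ± 0.155 in mannan stationary, 2.69% ± 1.23 in glucose exponential and 97.0% ± 0.352 in glucose stationary libraries. Whether ribosomal RNA was removed in the same way from all libraries is not given in the sources used here, so preparation and growth condition cannot be told apart for this share. Reads outside structural RNA therefore numbered 7767711 to 8478393, 6802863 to 8444570, 9222700 to 10834131 and 172856 to 261654 in the 4 groups. In the glucose stationary libraries the median gene had 11, 12 and 18 reads, and 150 to 216 genes had none. The tmRNA alone took 15.4% ± 1.49, 13.6% ± 5.01, 8.43% ± 2.08 and 0.815% ± 0.10 of the reads in the same order.

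Replicates correlated across genes at 0.995 to 0.997 in mannan exponential, 0.931 to 0.962 in mannan stationary, 0.990 to 0.996 in glucose exponential and 0.904 to 0.922 in glucose stationary libraries; genes are not independent replicates. No 2 libraries agreed within sampling noise (chi-square per degree of freedom at least 1.84). Within groups this ratio was 1.84 to 2.03 in glucose stationary and 101 to 392 in mannan stationary libraries. In mannan exponential libraries it was 5.41 to 14.3, and in glucose exponential libraries 18.5 to 38.6. The ratio also grows with read depth, which was lowest in the glucose stationary libraries. The first principal component held 62.4% of the variance and the next held 26.9%. Mannan stationary replicate 2 lay at 13.4 on the first component, against 42.4 and 37.1 for the other libraries of its group, and had a tmRNA share of 8.93%.

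The first comparison asked which genes differ between mannan and glucose during exponential growth. All 9 members of the mannan degradation list were higher on mannan. The alpha-galactosidase gene aga27A (CJA_0246, 315172 to 316386) rose most among them, with a log2 change of 5.30 ± 0.11 (adjusted p = 2.92e-08) and a level of 1217 ± 64.4 RPM against 25.2 ± 2.69 on glucose (n = 3 each). The mannanase genes man5D (CJA_0244), man26C (CJA_0236) and man26B (CJA_2480) rose by 4.37 ± 0.10, 3.64 ± 0.09 and 3.16 ± 0.09, to levels of 1967 ± 62.1, 885 ± 54.7 and 659.9 ± 37.4 RPM. Smaller rises were found for man5C (CJA_3470, 2.25 ± 0.25), man26A (CJA_2770, 1.89 ± 0.09), man5A (CJA_3338, 1.43 ± 0.12), man5B (CJA_2475, 0.71 ± 0.23, adjusted p = 0.0238) and man5E (CJA_3784, 0.63 ± 0.08). The rise of man5B did not pass without mannan exponential replicate 3 or without glucose exponential replicate 1, where its adjusted p reached 0.0910.

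**Figure D1:**
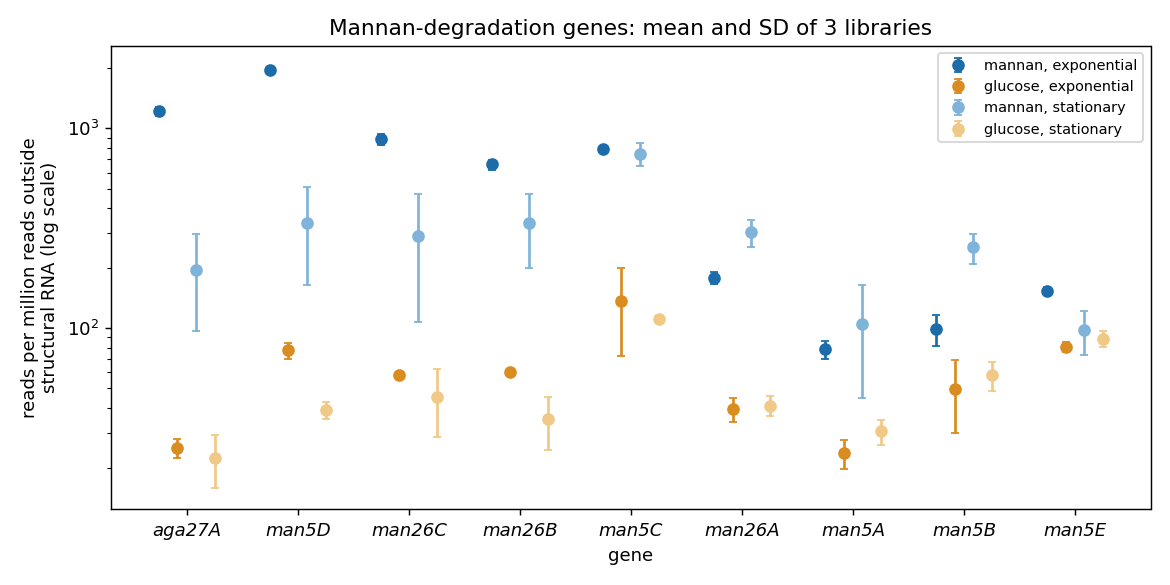
Levels of the 9 mannan degradation genes in the 4 groups, in RPM over reads outside structural RNA on a log axis; points and bars are the mean ± SD of 3 libraries. The gene aga27A stood at 1217 RPM in mannan exponential and 25.2 in glucose exponential libraries.

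Several of these genes are neighbours. The stretch from man26C to aga27A (302983 to 316386), chosen after its values had been seen, holds 11 features, of which 8 were higher on mannan and 3 lower. Within it, unk1 (CJA_0242), which encodes a mannosylglucose phosphorylase, rose by 4.68 ± 0.12 and unk2 (CJA_0243), which encodes a mannobiose epimerase, by 4.78 ± 0.10; their levels on mannan were 3529 ± 168 and 2349 ± 26.8 RPM. CJA_0241 rose by 3.84 ± 0.11. Outside this stretch, CJA_3246 (3875307 to 3878306) rose by 4.98 ± 0.15, from 220.1 ± 28.6 to 8524 ± 413 RPM, and CJA_3293 (3939508 to 3940728) by 4.23 ± 0.12. The 8 largest falls were much smaller, from -1.53 ± 0.09 for CJA_3602 (108 ± 12.2 against 252 ± 22.4 RPM) to -1.35 ± 0.13 for CJA_0473.

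Lists for other polysaccharides were also higher on mannan. Of the 18 xylan and arabinan genes 17 rose and none fell, with abf51A at 1.96 ± 0.10 and axe2C at 1.62 ± 0.08. Of 17 pectin genes 16 rose (17 when adjusted over the list alone), among them pga28A at 2.58 ± 0.15. In the list for xyloglucan and galactan 5 of 7 rose, with gal53A-1 at 2.31 ± 0.12. The starch and glycogen list had 13 of 17 risen, with amy13F at 1.93 ± 0.13. In the chitin list 5 of 7 rose, with the chitinase gene chi18D at 2.21 ± 0.19. In the list for cellulose and beta-glucan, here the cellulose list, 17 of 27 rose and 4 fell, with bgl2A at 2.73 ± 0.09 and bgl2C at 2.56 ± 0.18. Both genes were placed there by name and are not read as cellulase genes. The RefSeq symbol of bgl2C is galA. The gene bgl2A is also in the xyloglucan and galactan list, which shares xyl31A with the xylan and arabinan list, so these lists are not separate. Camera gave adjusted p = 7.22e-27 for the mannan list, 3.72e-09 for xylan and arabinan, 2.71e-05 for pectin, 3.14e-05 for xyloglucan and galactan, 0.000559 for starch and glycogen, 0.00109 for cellulose and 0.0246 for chitin. With an estimated correlation only the mannan list passed (adjusted p = 0.0313), and the other 6 had adjusted p = 0.471 to 0.519. Except for the pectin list, each of these counts was equal when adjusted over the list alone.

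Lists of translation, energy and biosynthesis genes were lower on mannan. Of 53 ribosomal protein genes 50 fell (51 when adjusted over the list alone). Among them rpmD stood at -0.90 ± 0.12 and 584 ± 31.1 against 881 ± 82.7 RPM. The fall of rpmD did not pass in 1 fit over all 12 libraries. Of 24 genes of ATP synthesis and respiration 23 fell, with the ATP synthase gene atpH at -1.01 ± 0.13, while cyoE, which encodes heme O synthase, rose by 1.82 ± 0.22. Among 78 amino acid biosynthesis genes 52 fell and 7 rose (53 and 7 when adjusted over the list alone). All 15 chaperone and protease genes fell, as did 7 of 8 genes of the tricarboxylic acid cycle. The glycolysis and Entner-Doudoroff list had 10 of 14 lower and 2 higher, with kdgA at -1.35 ± 0.16. The counts of these 3 lists and of the ATP list were equal when adjusted over the list alone. By camera the adjusted p was 4.99e-11 for ribosomal proteins, 4.39e-07 for ATP synthesis and respiration, 2.71e-05 for amino acids, 0.000167 for chaperones, 0.00177 for the tricarboxylic acid cycle and 0.00212 for glycolysis. With an estimated correlation these became adjusted p = 0.519 to 0.541. Falls also prevailed among translation factors (10 of 13), cell division (19 of 31, with 3 risen), type IV pili (15 of 23, with 5 risen) and type II secretion genes (8 of 13), with equal counts when adjusted over the list alone. For these 4 lists camera gave adjusted p = 0.000969, 0.00460, 0.00577 and 0.0111, or adjusted p = 0.519 to 0.624 with an estimated correlation.

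The edgeR test called 2430 of 3748 genes in exponential phase, 1291 higher and 1139 lower on mannan (53.1% higher). With library sizes only the split was 70.7% higher, over 2289 calls, and the median of all genes moved from 0.04 to 0.23. In 1 fit over all 12 libraries 1402 genes were called, 65.0% of them higher, and the falls within lists shrank to 5 ribosomal protein genes, 17 amino acid genes, 6 chaperone genes, 6 translation factor genes, 3 cell division genes, 5 type II secretion genes and 2 genes of the tricarboxylic acid cycle, while 11 cellulose genes rose. The authors' deposited table for this comparison lists 922 features at a false discovery rate under 0.05, 390 higher and 532 lower on mannan. Their test used normalized values rather than counts, so the 2 numbers are not from like tests.

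The next comparison asked which genes differ between the carbon sources in stationary phase. Of the 9 mannan degradation genes, 7 were higher on mannan (8 when adjusted over the list alone). The mannanase genes man26B, man26A and man5C rose by 2.77 ± 0.40, 2.35 ± 0.25 and 2.23 ± 0.21, with levels of 336 ± 136, 302 ± 46.3 and 745 ± 98.2 RPM on mannan against 35.0 ± 10.5, 40.9 ± 4.74 and 111 ± 4.52 on glucose (n = 3 each). The genes aga27A, man5D and man5B rose by 2.59 ± 0.46, 2.58 ± 0.40 and 1.62 ± 0.25, and man26C by 2.18 ± 0.49, or 1.48 without mannan stationary replicate 2. Values for man5A (1.28 ± 0.50, adjusted p = 0.0569) and man5E (-0.38 ± 0.26, adjusted p = 0.233) did not pass. In 1 fit over all 12 libraries man5E passed at -0.62. The gene man5A passed at 1.32 and 1.31 without mannan stationary replicate 1 or 2, and also with the replicate number as a block. Without mannan stationary replicate 3 man5A was 0.58 and did not pass, and it did not pass without any one of the glucose stationary libraries.

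The largest differences in stationary phase lay outside this list. CJA_0666 rose by 4.47 ± 0.41, with 304 ± 66.7 RPM on mannan against 9.68 ± 5.22 on glucose, CJA_1516 by 4.23 ± 0.34 (216 ± 27 against 7.94 ± 2.32), and CJA_0807 by 4.27 ± 0.49, or 5.37 without glucose stationary replicate 1. The other 5 of the 8 largest rises rested on 1 to 3 reads over the glucose stationary group. For these the ratio of pooled reads was 34 for sspB (95% interval 9.39 to 280.5), 30.5 for CJA_1813 (5.46 to 1204), 27.4 for CJA_1824 (9.38 to 133), 26.4 for CJA_0734 (4.73 to 1045) and 23.2 for CJA_3258 (4.15 to 916). Without glucose stationary replicate 1 or 3 CJA_3258 did not pass (largest adjusted p = 0.0706). On the lower side, CJA_3479 changed by -4.38 ± 0.27, with 124 ± 1.55 against 1809.5 ± 311 RPM, and CJA_1762 by -3.61 ± 0.24. CJA_0612, CJA_0611, gt4J-2, epsE, cel5H and CJA_0964 lay between -3.42 and -3.16, and without mannan stationary replicate 1 between -4.55 and -4.33.

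Of the other polysaccharide lists, those for xylan and arabinan, pectin, starch and glycogen, cellulose and chitin were higher on mannan, while the xyloglucan and galactan list did not pass (5 of 7 rose and 1 fell, 6 and 1 when adjusted over the list alone, camera adjusted p = 0.0526, or adjusted p = 0.326 with an estimated correlation). Of 18 xylan and arabinan genes 16 rose (17 when adjusted over the list alone), with the arabinofuranosidase gene abf43L at 3.53 ± 0.30 and 392 ± 71.6 against 22.5 ± 10.4 RPM. Of 17 pectin genes 13 rose (13 when adjusted over the list alone), with the pectin methylesterase gene pme8A at 2.88 ± 0.23. The starch and glycogen list had 10 of 17 higher and 2 lower (11 and 2 when adjusted over the list alone), with the amylase gene amy13A at 3.47 ± 0.26. The cellulose list had 15 of 27 higher and 2 lower and the chitin list 5 of 7 higher and 1 lower, with equal counts when adjusted over the list alone. The gene chi18D rose by 2.96 ± 0.22. Of 24 genes of ATP synthesis and respiration 14 rose and none fell (15 when adjusted over the list alone), with petB at 2.10 ± 0.22 and 1059 ± 174 against 172 ± 23.2 RPM. Mannan stationary replicate 2 stood apart for this list, with 0.990% of reads outside structural RNA against 0.545% and 0.546% in the other libraries of its group. Without it 11 rose, and the list's median was 0.91 in place of 1.47. Of 9 phosphate genes 5 rose and 1 fell (5 and 1 when adjusted over the list alone), with the phosphate uptake gene pstB at 2.92 ± 0.36. Camera gave adjusted p = 8.98e-07 for xylan and arabinan, 0.000517 for pectin, 0.00511 for mannan, 0.00511 for starch, 0.00532 for ATP synthesis and respiration, 0.0163 for cellulose, 0.0163 for chitin and 0.0499 for phosphate. With an estimated correlation none passed (adjusted p = 0.0989 to 0.652).

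Motility, sugar catabolism and nitrogen genes were lower on mannan in stationary phase relative to the median of all genes. That median was 0.30, and with library sizes only it moved to 6.06, with RLE factors to 0.10. Relative to it, the flagellar and chemotaxis list had a median of -1.11 (-1.08 with library sizes only, where its own median turned from -0.81 to 4.98), with 24 of 43 members fallen and 4 risen (25 and 4 when adjusted over the list alone). In this list flgM, the anti-sigma factor of flagellar synthesis, stood at 281 ± 98 against 791 ± 96.8 RPM. The glycolysis and Entner-Doudoroff list had a relative median of -1.13 (-1.10 with library sizes only, own median from -0.83 to 4.97), with 8 of 14 fallen and 4 risen (8 and 4 when adjusted over the list alone). Its Entner-Doudoroff genes kdgA and edd stood at -2.14 ± 0.23 and -1.76 ± 0.27. The nitrogen list had a relative median of -1.30 (-1.26 with library sizes only, own median from -1.0 to 4.81), with 5 of 11 fallen and 1 risen (7 and 1 when adjusted over the list alone). Of these nitrogen genes 9 fell without mannan stationary replicate 2. The type IV pili list had a relative median of -0.97 with either scaling (own median from -0.67 to 5.09), with 13 of 23 fallen and 4 risen (13 and 5 when adjusted over the list alone). The camera test gave adjusted p = 0.000276, 0.0388, 0.0239 and 0.00532 for the 4 lists in this order, and with an estimated correlation adjusted p = 0.526, 0.376, 0.294 and 0.326. Ribosomal protein genes did not pass (2 of 53 fell, 1 when adjusted over the list alone, camera adjusted p = 0.136), but 20 fell without mannan stationary replicate 2.

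In stationary phase the edgeR test called 2007 of 3755 genes, 1219 higher and 788 lower on mannan (60.7% higher). With library sizes only 99.8% of 3752 calls were higher, which turned every gene named here as lower, and in 1 fit over all 12 libraries 49.6% of 2285 calls were higher. The authors' deposited table lists 59 features at a false discovery rate under 0.05, 24 higher and 35 lower. Their test used normalized values rather than counts and gave no p-value for 636 features, so 59 and 2007 are not from like tests. Of the genes tested in both phases (3737), 706 were higher on mannan in both, against 420.5 for independent lists, and 300 were lower in both, against 240.2. Another 147 were higher in exponential and lower in stationary phase, and 228 were lower in exponential and higher in stationary phase. The 2 comparisons share no library. Both use glucose libraries from an earlier series, so carbon source and experiment cannot be told apart in this overlap.

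On mannan, stationary and exponential phase were compared next. CJA_3392 rose by 8.64 ± 0.36, from 16.0 ± 3.49 to 7689.9 ± 777 RPM (n = 3 each, adjusted p = 1.37e-05), CJA_0775 by 8.37 ± 0.40, from 52.5 ± 4.44 to 21045 ± 2498, and CJA_3391 by 7.10 ± 0.43. The urea transporter gene urtA (CJA_1241) rose by 6.35 ± 0.80 and xdhA, a xanthine dehydrogenase subunit, by 6.29 ± 0.80, or 5.49 without mannan stationary replicate 1. On the lower side, the ribosomal protein gene rpsF changed by -5.84 ± 0.43, from 2449.9 ± 151 to 52.3 ± 28.7 RPM, and metE, the cobalamin-independent methionine synthase, by -5.61 ± 0.27, from 3091 ± 359 to 76.7 ± 11.1. The rest of the 8 largest falls were the ribosomal protein genes rpsJ, rpsR, rplW, rpmG and rplI and a tuf copy (CJA_0684), whose value is uncertain because reads can be shared with the other copy (CJA_0697). The gene rpsJ reached -6.45 and rpmG -6.05 without mannan stationary replicate 2.

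The mannan degradation genes went both ways with phase. The genes aga27A and man5D changed by -2.93 ± 0.35 and -2.84 ± 0.35, man26C by -1.91 ± 0.40, man26B by -1.27 ± 0.28 and man5E by -0.94 ± 0.18. By contrast man5B rose by 1.08 ± 0.16 and man26A by 0.49 ± 0.17 (adjusted p = 0.0332). The rise of man26A did not pass when any mannan exponential library or mannan stationary replicate 1 was left out (adjusted p up to 0.125). Nor did it pass with the replicate number as a block. The fall of man26C reached -2.53 without mannan stationary replicate 2. Values for man5C (-0.37 ± 0.15, adjusted p = 0.0602) and man5A (0.13 ± 0.34, adjusted p = 0.742) did not pass, though man5C passed at -0.41 with RLE factors and with DESeq2 and at -0.39 and -0.43 without mannan stationary replicate 2 or 3. Without mannan stationary replicate 3 man5A changed sign and passed as a fall, at -0.40. As a list, 5 of 9 fell and 2 rose (6 and 2 when adjusted over the list alone), and camera gave adjusted p = 0.306.

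All 53 ribosomal protein genes fell in stationary phase on mannan (53 when adjusted over the list alone), and their joint share of reads outside structural RNA dropped from 11.5% ± 0.517 to 0.589% ± 0.353, with replicate 2 at 0.996% and the others at 0.394% and 0.376%. Of 13 translation factor genes 12 fell (12 when adjusted over the list alone), with tsf at -4.40 ± 0.24. Of 24 genes of ATP synthesis and respiration 22 fell and 1 rose (23 and 1 when adjusted over the list alone), with atpB at -2.60 ± 0.16 and mannan stationary replicate 2 again apart at 0.990% of reads. Of 14 glycolysis genes 12 fell (13 when adjusted over the list alone). The lowest was a triosephosphate isomerase gene at -3.88 ± 0.33, and both CJA_0185 and CJA_2671 carry its symbol, tpiA. In the flagellar list 37 of 43 rose and 1 fell (38 and 1 when adjusted over the list alone), with cheY (CJA_2140) at 1.89 ± 0.12. In the nitrogen list 7 of 11 rose and 4 fell (7 and 4 when adjusted over the list alone), with the nitrogen response regulator gene ntrC at 5.10 ± 0.30, from 137 ± 8.86 to 5639.5 ± 1179 RPM. In the stationary stress list 4 of 9 rose and 1 fell (4 and 1 when adjusted over the list alone). The ribosome modulation factor gene rmf (CJA_2157) rose by 4.73 ± 0.28, a katG gene for a catalase-peroxidase by 2.64 ± 0.14, and the stationary-phase sigma factor gene rpoS by 1.70 ± 0.13. Both CJA_0025 and CJA_2891 in this list carry the symbol katG. By camera the adjusted p was 1.82e-23 for ribosomal proteins, 9.10e-08 for translation factors, 1.09e-06 for ATP synthesis and respiration, 0.00193 for glycolysis, 2.76e-06 for flagella, 0.0479 for nitrogen and 0.00666 for stress. With an estimated correlation these became adjusted p = 0.406 to 0.462. Falls also prevailed among amino acid (60 of 78, with 9 risen; 61 and 9 when adjusted over the list alone), cell division (25 of 31, with 1 risen), chaperone (9 of 15, with 3 risen) and type II secretion genes (11 of 13). Rises prevailed among starch and glycogen (12 of 17, with 1 fallen; 13 and 1 when adjusted over the list alone) and xylan and arabinan genes (12 of 18, with 1 fallen). The other 4 counts were equal when adjusted over the list alone. For these 6 lists camera gave adjusted p = 2.94e-07, 3.48e-05, 0.0103, 0.0146, 0.00309 and 0.0259, and with an estimated correlation adjusted p = 0.406 to 0.522. Of 55 structural RNA features 38 fell and 6 rose (38 and 6 when adjusted over the list alone), with a median of -2.17 and camera adjusted p = 2.70e-15, or adjusted p = 0.406 with an estimated correlation. Counted on unique gene reads 27 were called, each of them lower, and in thinned libraries 16 fell and 3 rose; near-identical copies can share reads, so these values are uncertain.

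Between phases on mannan the edgeR test called 2569 of 3766 genes, 1319 higher and 1250 lower in stationary phase (51.3% higher). With library sizes only the split was 65.0% higher over 2614 calls, and the median of all genes moved from 0.11 to 0.41. The authors' deposited table, from their test on normalized values rather than counts, lists 754 features at a false discovery rate under 0.05. Of these 392 were higher and 362 lower.

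The same phases were compared on glucose, where CJA_3392 and CJA_0775 again had the largest rises among named genes, 10.49 ± 0.22 (8.35 ± 1.36 to 11234 ± 520.3 RPM, n = 3 each, adjusted p = 6.87e-12) and 10.02 ± 0.25 (31.1 ± 5.81 to 30172 ± 2061). The gene xdhA rose by 8.66 ± 0.21, and CJA_0565, CJA_0529, CJA_0571, CJA_0566 and CJA_3584 by 9.03 to 8.47. The largest falls were in ATP synthase and ribosomal protein genes: atpE changed by -6.74 ± 0.27, from 1088 ± 27.3 to 10.5 ± 6.77 RPM, atpF by -6.23 ± 0.23, rpmD by -6.22 ± 0.29 and rplF by -5.93 ± 0.22. Of the 9 mannan degradation genes, man5D changed by -0.93 ± 0.23 (adjusted p = 0.00332; -0.14 and not past the threshold in thinned libraries) and man26B by -0.75 ± 0.28 (adjusted p = 0.0308; up to 0.291 without glucose exponential replicate 1 or 3 or glucose stationary replicate 3). With RLE factors, with DESeq2 and in 1 fit over all 12 libraries man26B did not pass. The other 7 did not pass, with values from -0.33 for man26C to 0.45 ± 0.31 for man5A, and 1 fell when adjusted over the list alone (camera adjusted p = 0.962). In exponential phase on glucose these 9 genes together took 0.0551% ± 0.0101 of reads outside structural RNA, and 0.0470% ± 0.00540 in stationary phase.

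All 53 ribosomal protein genes fell on glucose too (53 when adjusted over the list alone), from 14.9% ± 0.945 to 0.474% ± 0.0487 of reads outside structural RNA. The ribosomal RNA share of 97.0% in the glucose stationary libraries is a value of these preparations and is not read as a change with phase. Of 24 genes of ATP synthesis and respiration 23 fell (23 when adjusted over the list alone), and of 8 genes of the tricarboxylic acid cycle 7 fell, with sucD (CJA_1510) at -3.25 ± 0.18 (7, and 1 risen, when adjusted over the list alone). The median of all genes was -0.16, and with library sizes only it moved to -5.56. Relative to it, the flagellar list had a median of 2.11 (2.07 with library sizes only, where its own median turned from 1.95 to -3.49), with 40 of 42 risen (41 when adjusted over the list alone). The genes flgM and fliS, the latter for a flagellin chaperone, rose by 3.49 ± 0.12 and 3.16 ± 0.12. The nitrogen list had a relative median of 2.66 (2.60 with library sizes only, own median from 2.50 to -2.96), with 7 of 11 risen and 3 fallen (7 and 3 when adjusted over the list alone). Among the risen were ntrB (CJA_0528) at 8.07 ± 0.26 and ntrC at 6.24 ± 0.17. The stress list had a relative median of 1.81 (1.75 with library sizes only, own median from 1.65 to -3.81), with 6 of 9 risen (6 when adjusted over the list alone). Among these were rmf at 4.66 ± 0.18 and rpoS at 2.57 ± 0.11. Camera gave adjusted p = 1.36e-35 for ribosomal proteins, 3.30e-13 for ATP synthesis and respiration, 0.000380 for the tricarboxylic acid cycle, 2.13e-11 for flagella, 0.000319 for nitrogen and 0.00424 for stress, and with an estimated correlation each had adjusted p = 0.417. Falls also prevailed among translation factors (12 of 13, with 1 risen), amino acid (60 of 78, with 11 risen), cell division (29 of 31, with 2 risen) and glycolysis genes (10 of 14, with 1 risen), with equal counts when adjusted over the list alone. For these 4 lists camera gave adjusted p = 9.89e-08, 7.47e-07, 7.76e-05 and 0.0132, and adjusted p = 0.417 to 0.540 with an estimated correlation.

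**Figure D2:**
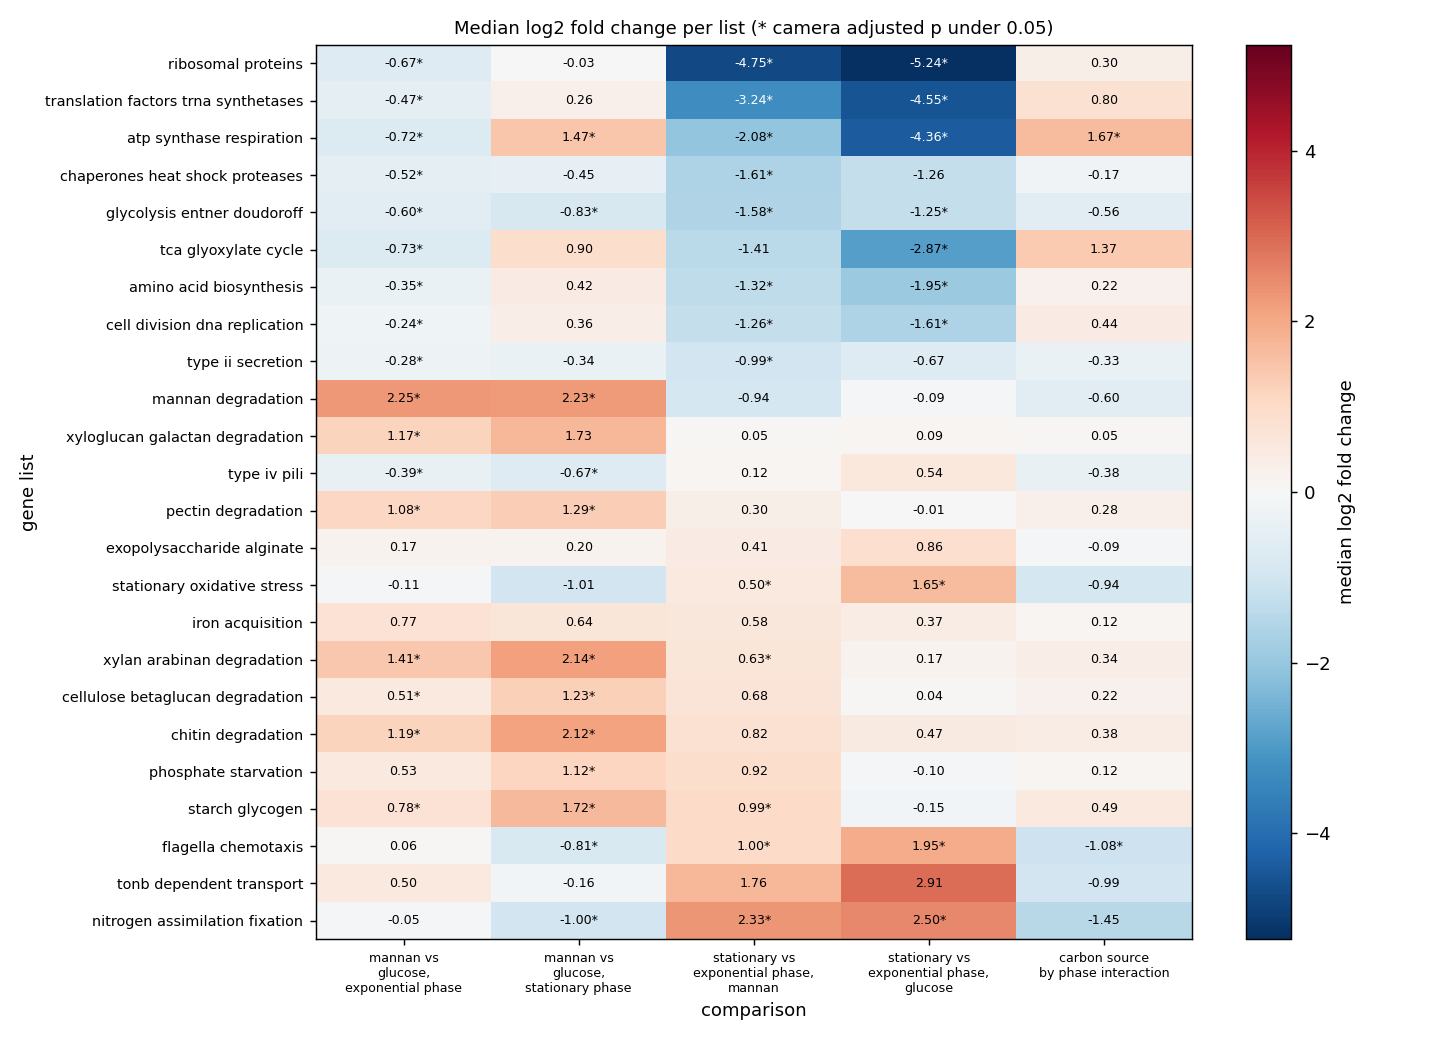
Median log2 change of each of 24 gene lists in the 4 comparisons and the interaction, with an asterisk where camera at its preset correlation gave an adjusted p under 0.05; with an estimated correlation only the mannan list in exponential phase passed. The ribosomal protein list stood at -4.75 between phases on mannan and -5.24 on glucose. Among lists with an asterisk, library sizes only turned the medians of flagellar, glycolysis, nitrogen and pili genes to positive between carbon sources in stationary phase. This scaling turned those of flagellar, nitrogen and stress genes to negative between phases on glucose, and that of flagellar genes to positive in the interaction. Lists without an asterisk are left out of this account.

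Between phases on glucose the edgeR test called 2518 of 3696 genes, 1130 higher and 1388 lower in stationary phase (44.9% higher). Under library sizes only, 2.11% of 3655 calls were higher. Of the genes tested on both carbon sources (3695), 766 rose with phase on both, against 390.5 for independent lists, and 946 fell on both, against 469. Another 86 rose on mannan and fell on glucose, and 66 fell on mannan and rose on glucose.

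The interaction asked which phase changes differ between mannan and glucose, and positive values mean a change that is more positive on mannan. The phase change of aga27A was lower on mannan by -2.92 ± 0.63 (adjusted p = 0.00224), that of man5D by -2.00 ± 0.48, that of man5E by -1.22 ± 0.26 and that of man26C by -1.66 ± 0.60 (adjusted p = 0.0376). The last did not pass in 8 of the 12 fits that left out 1 library (adjusted p up to 0.124) and stood at -2.28 without mannan stationary replicate 2; the other 5 members did not pass in the full fit. Of these, man5B passed at 0.83 without glucose exponential replicate 3 and man5A at -0.92 without mannan stationary replicate 3. CJA_3293 had the most negative value, -5.32 ± 0.34 (adjusted p = 2.79e-07), with 544 ± 11.9 and 43.9 ± 5.84 RPM in exponential and stationary phase on mannan and 23.6 ± 5.01 and 57 ± 10.8 on glucose (n = 3 each). The gene manC (CJA_3307, 3957249 to 3958451) had -4.97 ± 0.31, with 1449.5 ± 68.7 and 196 ± 57.3 on mannan and 191 ± 5.85 and 598 ± 76.3 on glucose. Under the naming rule the most positive values were 4.38 for sspB and 3.85 for CJA_0807. Next came pheS, which encodes a subunit of phenylalanyl-tRNA synthetase, with 3.71 ± 0.43, or 4.61 without glucose stationary replicate 3. The gene thiD, a kinase of the thiamine pathway, had 3.61 ± 0.47. Both sspB and pheS had few reads in the glucose stationary libraries.

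Relative to the median of all genes (-0.04, and 5.75 with library sizes only), the flagellar list had an interaction median of -1.03 (-1.02 with library sizes only, where its own median turned from -1.08 to 4.73), with 32 of 43 members lower (33 when adjusted over the list alone). In it motB had -1.95 ± 0.22. The ATP synthesis and respiration list had a relative median of 1.72 with either scaling, with 19 of 24 higher (21 when adjusted over the list alone, and 12 over all genes without glucose stationary replicate 1). Its own median was 1.67, or 1.26 without mannan stationary replicate 2. Here sdhD (CJA_1502) had 2.90 ± 0.33 and petA 2.71 ± 0.35. Camera gave adjusted p = 3.05e-07 for flagella and 3.31e-07 for ATP synthesis and respiration, and with an estimated correlation adjusted p = 0.907 for both. The mannan list as a whole did not pass (4 of 9 lower, 4 when adjusted over the list alone, camera adjusted p = 0.393).

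**Figure D3:**
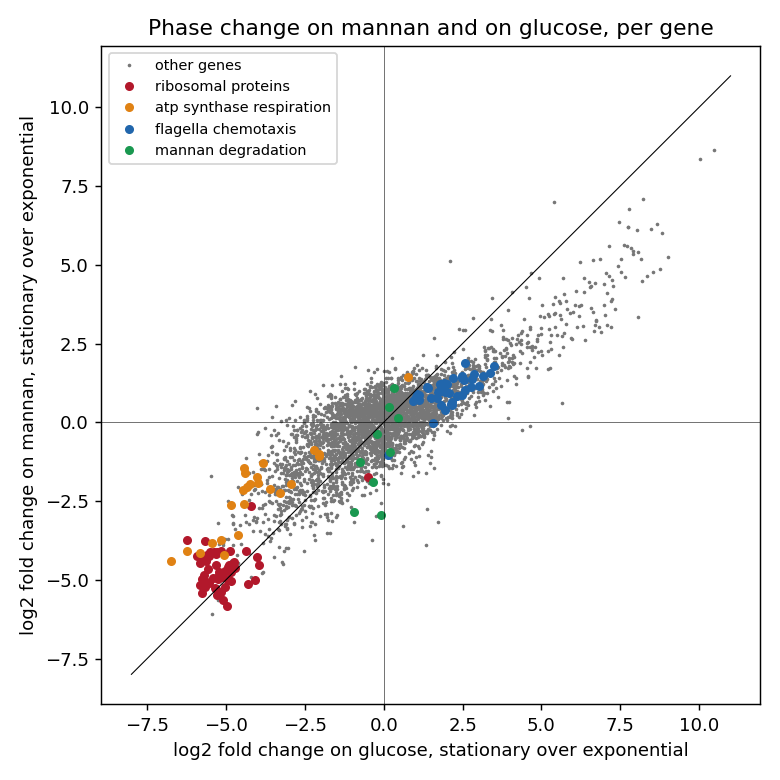
Log2 change from exponential to stationary phase on mannan against that on glucose, 1 point per gene for 3614 of the 3644 genes tested in both; the 30 genes at 0 in every glucose stationary library are not drawn. The gene CJA_3392 lies at 8.64 on mannan and 10.49 on glucose.

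For the interaction the edgeR test called 1724 of 3767 genes, 728 higher and 996 lower (42.2% higher). With library sizes only 99.8% of 3758 calls were higher, which turned every gene named here as lower. Carbon source and experiment cannot be told apart in this test or in the comparisons between carbon sources.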

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

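In this part the test with thinned libraries was chosen only after the data had been seen.

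The number of genes whose phase change differed between mannan and glucose, 1724 of 3767 by the edgeR interaction test, was singled out because it tests a difference between groups directly. Among 100 splits of the 12 libraries, the real one included, 2 gave as many genes. The highest other split called 2453 genes, more than the real one. It kept the 3 mannan exponential and the 3 glucose exponential libraries together while it mixed stationary libraries. Its contrast thus set all stationary against all exponential libraries, so it tested the phase difference. Splits that mix groups carry the phase and carbon source differences into the spread or, as here, into the contrast. They therefore do not settle whether chance is excluded.

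The 10 genes with the largest such differences by the naming rule had edgeR adjusted p from 2.79e-07 to 0.00411. The log2 difference, mannan minus glucose, was 4.38 for sspB, 3.85 for CJA_0807 (4.89 without glucose stationary replicate 1), 3.71 for pheS (4.61 without glucose stationary replicate 3), 3.64 for CJA_2090 and 3.61 for thiD. Both sspB and CJA_2090 had 2 reads over the glucose stationary group. Their ratios of pooled reads, glucose exponential over glucose stationary, were 17.2 (95% interval 4.76 to 142) and 12.4 (3.42 to 102). The reads of pheS in the glucose stationary libraries were 0, 2 and 5. The difference was -5.32 for CJA_3293, -4.97 for manC and -4.80 for CJA_0572. It was -5.08 for CJA_3465 (zigA), -5.72 without glucose stationary replicate 2 and -4.13 without replicate 3, and -4.69 for CJA_1306, -5.34 without glucose stationary replicate 2. With library sizes only, all 5 negative values became positive, as did the median of all genes.

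Phase changes were smaller on mannan than on glucose: of 2482 genes called on mannan and tested on both, 55.2% had a larger change in the same direction on glucose, with median sizes of 1.11 and 1.43. In the reverse selection, 14.4% of 2479 genes called on glucose had the larger change on mannan. With each library thinned to 172856 reads outside structural RNA the share was 56.1% (56.8% ± 1.13, mean ± SD over 10 draws, lowest 54.2%), which argues against unequal numbers of such reads as the whole cause. Without mannan stationary replicate 2, which lay nearest to the exponential libraries, it was 52.8%, between the bounds set for that explanation, so this library and a response to the carbon source, itself confounded with the experiment, cannot be told apart.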

How the results depend on the processing

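Thinned libraries and unique gene reads were chosen after the data had been seen; the other settings were fixed before. Other pseudocounts and recovered reads were not run because the values were counts. The counts of called genes (2430, 2007, 2569, 2518 and 1724 for mannan against glucose in exponential and stationary phase, phase on mannan, phase on glucose and the interaction) moved by over 1.5 times in few settings. All 4 groups in 1 fit gave 1402 in exponential phase. Library sizes only gave 3752 between carbon sources in stationary phase and 3758 in the interaction. Thinned libraries gave 1689 between phases on mannan and 1055 in the interaction, where fewer reads enter. The stricter threshold gave 83, 470, 560, 1090 and 330, being stricter by construction. Of these calls 96.4%, 83.2%, 32.5%, 42.1% and 41.5% were higher, against 53.1%, 60.7%, 51.3%, 44.9% and 42.2% at the main threshold. Elsewhere the cause was not tested. With 1 library left out the counts ranged from 1985 to 2574, 1560 to 2111, 2044 to 2658, 2310 to 2565 and 1512 to 1847. Named genes called in the full fit, with those of the wider reading, that were called in every fit with 1 library left out numbered 70 of 71, 65 of 67, 68 of 69, 46 of 47 and 20 of 22.

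Camera with the preset correlation passed 17, 13, 14, 10 and 2 of 25 lists. With an estimated correlation it passed 1, 0, 0, 0 and 0 (2, 3, 1, 1 and 0 at an unadjusted p under 0.05), and fry passed 22, 15, 22, 19 and 10. The structural RNA list between carbon sources in stationary phase had a median of 0.83 and a mean of 0.62 while camera ranked it as lower (adjusted p = 0.00448, and 0.483 with an estimated correlation). Median, mean and test also differed in sign for nitrogen, stress and structural RNA genes in exponential phase, exopolysaccharide genes in stationary phase, xyloglucan genes between phases on mannan, pectin, starch and xyloglucan genes between phases on glucose, and chaperone, iron, structural RNA and xyloglucan genes in the interaction; of these none passed camera.

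The labels do not say whether equal replicate numbers in the 2 phases on a carbon source mark the same culture. With 3 libraries per group the values could not settle it. Between carbon sources equal numbers cannot mark the same culture, because the glucose libraries were re-used from an earlier series. The block is thus arbitrary in those comparisons and in the interaction. Deviations of same-numbered libraries correlated at -0.683 to -0.121, -0.00329 to 0.0281, -0.265 to 0.178 and -0.0313 to 0.00872 in the 4 comparisons of 2 groups. In the same order 0, 4, 1 and 0 of 6 libraries correlated best with their own number. With the replicate number as a block the counts were 2046, 2008, 2389, 2501 and 1639; of the named genes man26A was no longer called between phases on mannan (0.47), CJA_0026 no longer in the interaction, and man5A was newly called between carbon sources in stationary phase (1.26).

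Reversals came mostly with library sizes only, where 97.0% ribosomal RNA in the glucose stationary libraries enters the scale and the median of all genes moves to 6.06, -5.56 and 5.75 in the 3 comparisons with that group. Between carbon sources in stationary phase the values became 5.42 for man5E, 1.40 for CJA_3479, 2.17 for CJA_1762, 2.28 for CJA_0612, 2.35 for CJA_0611, 2.41 for gt4J-2, 2.41 for epsE, 2.47 for cel5H, 2.49 for CJA_0964, 2.40 for CJA_0381, 3.95 for fliG, 3.74 for flgM (CJA_1936), 4.27 for fliS (CJA_1701), 3.64 for kdgA, 4.07 for pgl, 4.00 for edd, 3.99 for gltD, 4.81 for glnE, 4.15 for pilG, 4.35 for pilT and 4.45 for pilO. Between phases on glucose they became -4.96 for man5A, -5.22 for man5E, -5.12 for man5B, -5.26 for man26A, -1.94 for flgM, -2.28 for fliS, -2.41 for motB, -1.57 for katG (CJA_2891), -0.81 for rmf (CJA_2157) and -2.88 for rpoS. In the interaction they became 4.60 for man5E, 2.90 for aga27A, 3.84 for man5D, 4.19 for man26C, 5.23 for man26B, 5.42 for man5A, 5.60 for man5C, 0.47 for CJA_3293, 0.66 for CJA_3465, 0.80 for manC, 0.98 for CJA_0572, 1.07 for CJA_1306, 0.97 for CJA_1305, 3.84 for motB, 4.11 for motA1 and 4.04 for fliS.

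A few values that did not pass the test in the full fit also changed sign, and the cause was not tested. Between phases on glucose aga27A was 0.0106 with RLE factors and 0.00369 with DESeq2, and man26C was 0.23 in thinned libraries; with 1 library left out, aga27A ranged from -0.265 to 0.0396 and man5C from -0.33 to 0.19. Between phases on mannan man5A ranged from -0.40 to 0.37 with 1 library left out, and the fall of -0.40, without mannan stationary replicate 3, passed the test. In the interaction man5B was -0.0942 and man26A -0.55 in thinned libraries. Depth limits the glucose stationary group most: there 3 reads over the group correspond to 4.79 RPM. For features at 0 in that group the fold between carbon sources was at least 7.95-fold higher on mannan for CJA_0026, 6.81-fold for CJA_3059, 4.85-fold for CJA_0034, 4.40-fold for CJA_0933 and 4.19-fold for CJA_3533.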

Other observations

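Among the tests in this part, those of the size factors and of the correlation with the phase change were chosen only after the results had been seen, as were the thinned libraries and the groups of neighbouring genes; the rest were planned.

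A group of 14 neighbouring features from CJA_0611 to epsE (744158 to 759497) was higher in stationary phase on both carbon sources and lower on mannan than on glucose. All 14 rose with phase, with a median of 2.88 on mannan and 6.27 on glucose, and all 14 were lower on mannan in stationary phase, with a median of -3.07. Their summed level was 7270.2, 631 and 3779 RPM in mannan stationary replicates 1, 2 and 3, against 22137, 26311 and 23875 on glucose. In exponential phase it was 332 to 471 on mannan and 242 to 341 on glucose. The interaction was lower for all 14, with a median of -3.41. With library sizes only, the difference between carbon sources in stationary phase became positive, 2.35 for CJA_0611, 2.28 for CJA_0612 and 2.41 for epsE, against a median of 6.06 for all genes.

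A run of 8 features from CJA_0565 to CJA_0572 (691864 to 700449) also rose with phase, with a median of 4.72 on mannan and 8.27 on glucose. Its summed level was 23832, 2842 and 21141 RPM in mannan stationary replicates 1, 2 and 3 and 49601, 42110.2 and 40775 on glucose. In exponential phase 7 of the 8 were higher on mannan, with a median of 1.76 and sums of 398 to 513 against 84.5 to 144. CJA_3465 (zigA) and CJA_1306 varied widely within the glucose stationary group, with 271, 5 and 853 and with 582, 7 and 939 reads in replicates 1, 2 and 3.

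Calls between carbon sources in stationary phase leaned to higher on mannan, 60.7% of 2007. With each library thinned to 172856 reads outside structural RNA, 58.9% were higher (57.9% to 59.3% over 10 draws), which argues against unequal numbers of such reads as the whole cause. The share was 53.4% with median-ratio size factors, 49.6% in 1 fit of all 4 groups, 53.0%, 54.9% and 56.2% without mannan stationary replicate 1, 2 or 3, and 61.1% to 62.8% without a glucose stationary library, so the choice of size factors may account for the lean, which also depends on which mannan libraries enter. With all structural RNA left out 60.4% were higher. Leaving out only rRNA and tRNA features also gave 60.4% and kept 1980 of the 2007 calls. A setting that leaves nearly all calls as they were cannot test ribosomal RNA in the library size, so that explanation stays undecided. A difference due to the carbon source stays open and is confounded with the experiment.

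The differences between mannan and glucose in exponential phase followed the phase change on mannan: across 3692 genes, which are not independent replicates, the Spearman correlation was 0.565 and the covariance 0.422. Both comparisons use the mannan exponential libraries, which with no effect gave -0.474 and -0.0280 on average over 20 simulations. A candidate explanation is that the mannan cultures were nearer to stationary phase when sampled. The correlation with gene length was 0.117, which argues against a length bias as the whole cause. A response to the carbon source itself remains open and was not tested apart from the experiment.

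The edgeR counts of 2430 and 2007 genes between carbon sources in exponential and stationary phase, and of 2569 and 2518 between phases on mannan and glucose, were set against the other splits of the same 6 libraries. In each case 1 of 10 splits, the real one, gave as many genes, and the highest other count was 0. At an unadjusted p under 0.05 the highest other counts were 78, 35, 67 and 33, against 2566, 2228, 2680 and 2598 for the real splits; no other tool was run on the splits. The splits are too few for a share under 0.05, since the smallest share is 0.1. Each other split also mixes the 2 groups and carries their difference into the spread. Its low count therefore does not show what chance alone would give.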
